A study of Sus scrofa with 6 samples.

How the data were processed

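Total RNA of 2 muscles of 3 pigs was extracted with TRIzol and RNeasy columns, labelled with biotin by in vitro transcription and hybridised to Affymetrix porcine GeneChips, per the labels' protocols. The submitters' processing notes name MAS5 version 2.3.1, with no role given. The scaling between arrays and the summarisation of probes are not given in the sources used here.

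The series value table holds, as deposited, log2 expression centred by the authors on each probe set's own median over the 6 arrays. This was found from the values, since the median over the 6 arrays was 0 for each of the 24123 probe sets within 5e-07, and 2 to the difference of the muscle means gave the authors' fold. Centring removes the intensity level, so no probe set could be called dim or bright. The authors' comparison table gives, per the file headers, a p-value of an unpaired test with asymptotic computation and cut-offs of 0.05 on p and 1.5 on fold, for all entities and with no adjustment for multiple tests named. Its fold is, in the authors' deposited table, a linear ratio of the larger to the smaller muscle mean. The test was checked against the values: an equal-variance unpaired test gave the same p-values as the authors' table to within 4.74e-07. Its "up" means higher in longissimus dorsi.

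The 188 control probe sets were left out, which left 23935. Soleus was set against longissimus dorsi with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the deposited log2 values without further normalization, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined asked for a filter at the 40th percentile of mean signal, a variance trend on intensity and the brightest probe set per gene. None of these can be formed from centred values, so all non-control probe sets were tested without a trend. A trend on the mean centred value and the authors' test with Benjamini-Hochberg adjustment were added as alternatives after seeing the data. The alternatives fixed before the data were examined that could be run were quantile normalization, the replicate number as a block, the threshold of the authors' table and leaving out each array in turn. The fit was also run on simulated data with 200 changed probe sets among 23935, in 3 arrays against 3. Their noise was normal, independent between probe sets and equally wide on all arrays, with the real residual SDs shuffled over probe sets. The real arrays were not equally wide, and the adjusted threshold is stricter where fewer probe sets change than the 200 simulated. The shares called need therefore not hold for the real data. The fit called 34% of those changed by 1 on the log2 scale, 82% of those changed by 2, 96% at 3 and 100% at 4. It also called 8 unchanged ones.

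Gene names were taken from the authors' table alone, which names genes for its 550 kept probe sets. Of these, 89 had a gene symbol and 333 a gene or protein name, 241 of them without a symbol and through similarity to a protein of another species, and 217 had none. The planned count of genes over the array and the planned limma gene set tests need names for all probe sets and were not run. In their place the genes of 19 lists fixed before the data were examined were looked up in that table, by symbol and, for 26 probe sets, by a title matched by hand. The genes with higher and lower medians in soleus were counted, and lists with 5 or more named genes were set against the other named genes with a two-sided Fisher's exact test, chosen after the data were seen (SciPy 1.17.1, Python 3.11.15). A count adjusted over the list alone was not made, since members outside the kept probe sets have no name here.

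Named genes followed a rule written before the data were examined: in each direction the 12 largest differences among those past the threshold with no overlap between muscles, filled up to 12 by the smallest p and then given as not past it. From each list up to 4 members past the threshold, or the 2 with the smallest p, were named, and MYH7, MYH2, MYH1, MYH4, TNNT1, TNNT3, PPARGC1A, MB and PITX1 where named. The rule was applied to the named genes of the authors' table, each represented by its probe set with the smallest p. The probe set without a gene name, a fructose 1,6-bisphosphatase probe set and further list members given as examples were added after their values were seen. Pigs of one litter share parents, and n counts arrays of 3 pigs per muscle.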

Results

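Skeletal muscle RNA of 3 Meishan gilts of one litter, aged 150 days, was measured on 6 Affymetrix porcine GeneChips, with 3 arrays of longissimus dorsi and 3 of soleus. The longissimus dorsi is a back muscle that the labels class as fast-twitch and glycolytic. The second muscle is called soleus in the sample titles and SE in the protocol, where it is described as oxidative and sampled in its deep part. It is called soleus here, as in the titles. Both muscles came from the same 3 pigs, and the labels number the samples of each muscle as biological replicates 1 to 3. The number of arrays limits the precision of every value. Each value is a log2 expression relative to the probe set's own median over the 6 arrays, so differences between muscles can be read from it and absolute levels cannot.

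The series compared a white with a red muscle, and few transcripts separated them past the adjusted threshold. OCA2, which encodes a melanosomal membrane protein of the pigmentation pathway, fell in soleus, from 1.87 ± 0.39 in longissimus dorsi to -1.79 ± 0.22 (SD, n = 3 arrays each). This was a 12.7-fold difference (log2 difference -3.66, SE 0.23, limma adjusted p = 0.00321). The other probe set past the threshold, which has no gene name, rose in soleus, from -2.38 ± 0.03 to 2.56 ± 0.20. This 30.6-fold difference was the largest of all probe sets (log2 difference 4.94, SE 0.16, adjusted p = 3.77e-05). For this probe set 2 of the 3 longissimus dorsi values were equal within 1e-06 (the 2 lowest values were so in 103 probe sets and the 2 highest in 91). Since signal over background is unknown, it is open whether these longissimus dorsi values lie at the background. There the fold would be a lower bound and the SD too small. The same is open for OCA2 in soleus, where replicates 1 and 3 had close values (-1.924 and -1.925). The named members of the extracellular matrix list (10 genes) and of the tendon list (5 genes) all had higher means in soleus, but they came from probe sets kept for differing in these samples and 0 passed on their own.

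In all, 2 of 23935 probe sets passed an adjusted p under 0.05, 1 in each direction. At an unadjusted p under 0.05 there were 2025 probe sets, or 8.46% of those tested, where 5% would be reached by chance, and 2 of the 9 other ways to part the 6 arrays into 3 and 3 gave more (2289 and 2151). With at least a 1.5-fold difference as well there were 1219, of which 692 were higher in soleus and 527 lower. The 3 arrays of one muscle did not overlap those of the other in 3395 probe sets (14.2%), against 10% by chance. Differences were mostly small, with 338 probe sets at 2-fold or more, 13 at 4-fold or more and 3 at 8-fold or more. The fit took the arrays as unpaired, since the labels do not say that a replicate number marks a pig. As both muscles came from the same 3 pigs, the 6 arrays are not independent. The SEs and p-values of this fit leave that out. With the replicate number as a block the adjusted count was 7. It was 6 after quantile normalization, 10 with a variance trend on the mean centred value and 4 without soleus replicate 3. OCA2 lost its call without longissimus dorsi replicate 1 (adjusted p = 0.0564, with a range of 0.000121 to 0.253 over 10 alternative settings). The count of 1219 became 797 without longissimus dorsi replicate 2. Its lean towards soleus was lost without soleus replicate 1 (2501, with 1235 higher and 1266 lower). The lean was nearly gone with the block (1688, with 850 higher and 838 lower). It was larger without soleus replicate 3 (932, with 604 higher and 328 lower).

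Among the 12 named genes with the smallest p on the side of soleus, none passed the threshold in this fit. With quantile normalization or a variance trend, 5 did. All had 3 soleus values above the 3 of longissimus dorsi. The muscles did not overlap in any of the 549 kept probe sets tested, so this follows from how the genes were kept. Elastin, the core protein of elastic fibres, had an adjusted p of 0.0878 (log2 difference 1.51, SE 0.15), but 1 of its 5 listed probe sets ran the other way (-1.24). Tenascin C, a matrix glycoprotein, differed by 1.41 (SE 0.17), tenascin-X by 1.55 (SE 0.18) and annexin A8 by 2.41 (SE 0.28), all at an adjusted p of 0.0885. The secreted Wnt antagonist SFRP4 had a mean of 1.02 ± 0.44 in soleus against -0.72 ± 0.19 in longissimus dorsi. Cardiac alpha actin, an actin also made by developing skeletal muscle, differed by 2.91 (SE 0.44) at an adjusted p of 0.215. Homeobox protein A10 (symbol HOXD10A), trophoblast glycoprotein, transforming growth factor beta induced, tubulin beta 2B, the transmembrane prostate androgen induced transcript and the SA hypertension-associated homolog differed by 0.93 to 1.55.

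On the side of longissimus dorsi, OCA2 passed and the other 11 of the 12 genes did not in this fit, although 4 did with quantile normalization or a variance trend. Arginase type II, the mitochondrial form of the enzyme that splits arginine, had a mean of 1.75 ± 0.64 in longissimus dorsi and -1.61 ± 0.54 in soleus (log2 difference -3.36, SE 0.37, adjusted p = 0.0885). With the replicate number as a block in limma, arginase type II passed (adjusted p = 0.00190). A further arginase probe set differed by -2.74. Renalase, a flavoprotein, differed by -1.17 (SE 0.14, adjusted p = 0.0885), with SDs of 0.03 and 0.05 within the muscles. The ubiquitin-conjugating enzyme E2E 3 had 3 listed probe sets at -1.54, -1.36 and -0.99. Ribonuclease H2 subunit B differed by -2.16 (SE 0.33), microsomal glutathione S-transferase 2 by -1.49, ART3 by -1.42 and nucleosome assembly protein 1-like 2 by -1.37. Testis expressed 9, nudix-type motif 15, myelin basic protein and a slow myosin heavy chain transcript differed by -1.36 to -0.91.

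The extracellular matrix list, fixed before the data were examined, had 10 of its 21 genes named among the probe sets that the authors' comparison kept, and all 10 had higher means in soleus. Of the other named genes there, 163 were higher and 115 lower in soleus (Fisher's exact test, two-sided, p = 0.00689, adjusted p = 0.0138 over the 2 lists with 5 or more genes). These genes had been kept because they differed in these samples, and matrix genes vary together, so the test is not independent evidence and its p is too small. The list members with the smallest p were COL12A1, a fibril-associated collagen (log2 difference 1.06, SE 0.18), and COL1A1, a chain of type I collagen (1.63, SE 0.27), both at an adjusted p of 0.269. Over the 14 probe sets of the list the differences ran from 0.64 to 1.82, and 0 passed in limma. The tendon list had 5 of its 12 genes named, TNC, FMOD, COMP, THBS4 and CLEC3B, all with higher means in soleus. With 5 genes this is the most extreme outcome in that direction and gives p = 0.161 (Fisher's exact test, adjusted p = 0.161), so the test could not have passed there and is silent on the list. Fibromodulin, a collagen-binding proteoglycan, had a mean of 0.72 ± 0.49 in soleus against -0.92 ± 0.45 in longissimus dorsi. The mean over the 10 matrix genes was 0.84, 0.30 and 0.96 in soleus replicates 1, 2 and 3, and -0.48, -0.49 and -0.42 in those of longissimus dorsi. Soleus replicate 3, the highest of these, was also the array that stood apart from the rest.

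**Figure D1:**
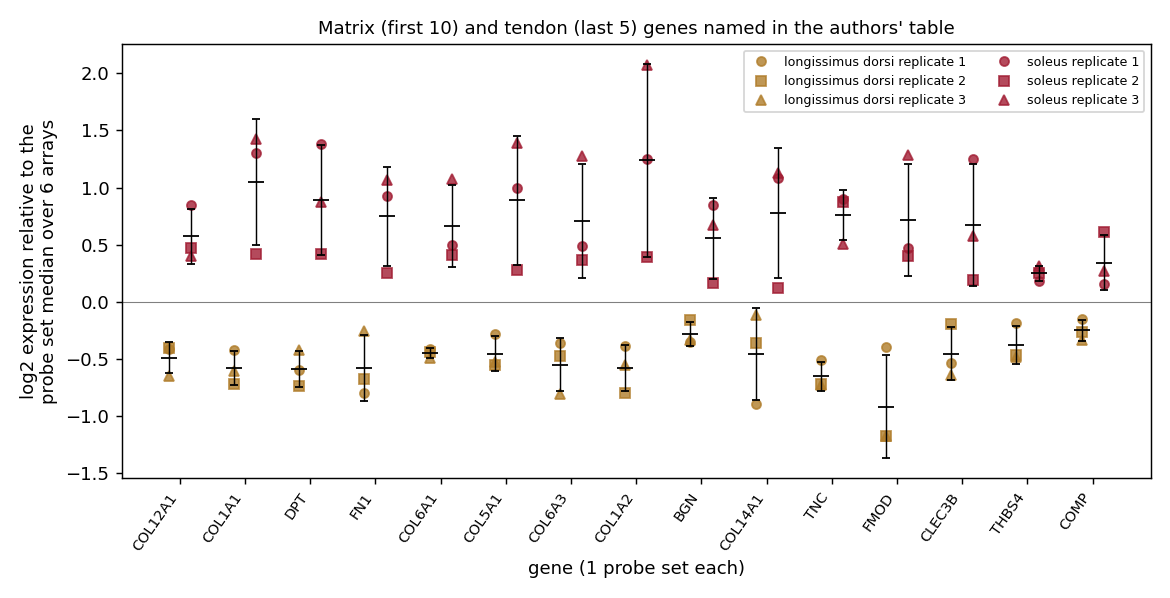
Log2 expression relative to the probe set median over 6 arrays (vertical axis) for 10 matrix and 5 tendon genes (horizontal axis), 1 probe set each, with 1 symbol per array, and a dash and bars for the mean and SD of the 3 arrays of a muscle. Every soleus array lies above every longissimus dorsi array in all 15 genes, which had been kept for differing in these samples.

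Genes of the contractile apparatus ran both ways and none passed. Slow-type myosin binding protein C (MYBPC1), a thick filament protein, had means higher in soleus by 1.14 and 1.19 on 2 probe sets (adjusted p = 0.269 and 0.283). Calsarcin 1 (MYOZ2), a Z-disc protein of slow fibres, differed by 0.86 and FHL1 by 0.62. A probe set titled as similar to bovine slow myosin heavy chain went against these 3 genes of its list, with 0.51 ± 0.21 in longissimus dorsi and -0.47 ± 0.18 in soleus (log2 difference -0.98, SE 0.18, adjusted p = 0.306). MYH4, the fast type IIb myosin heavy chain, was the 1 named gene of the fast list, at -0.59 (SE 0.18, adjusted p = 0.479). Of the glycolysis list, 1 gene was named, the muscle fructose-1,6-bisphosphatase FBP2, at -0.90 (SE 0.23, adjusted p = 0.404), whereas a probe set titled fructose 1,6-bisphosphatase, outside the list, differed by 1.09 (adjusted p = 0.359). MEF2C, a transcription factor of muscle differentiation, was the 1 named oxidative fibre regulator, at 0.66 (SE 0.17, adjusted p = 0.416). Carbonic anhydrase II differed by -2.07 (SE 0.42, adjusted p = 0.321) and VEGFA, an angiogenic factor, by 0.74 (SE 0.23, adjusted p = 0.482), both of the haem and oxygen supply list. A homeobox gene of the position list had higher means in soleus on all 4 of its listed probe sets, by 1.03 to 1.18 (adjusted p = 0.215 to 0.306). Probe sets that did not differ enough to be kept have no name here. For any gene, agreement among its listed probe sets is therefore not independent evidence. The authors' table titles the 4 homeobox probe sets as homeobox protein A10 but gives them the symbol HOXD10A, so that they are called HOXA10 by title alone. MEIS1, of the same list, differed by -0.71 (adjusted p = 0.433).

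**Figure D2:**
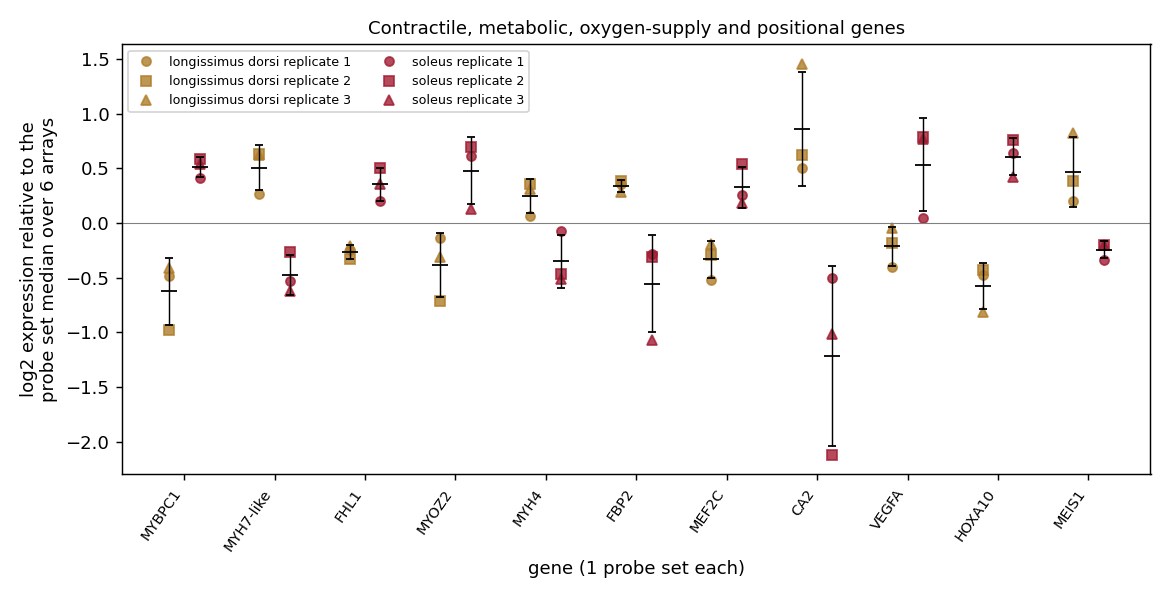
Log2 expression relative to the probe set median over 6 arrays (vertical axis) for 11 genes of the contractile, metabolic, oxygen supply and positional lists (horizontal axis), drawn as single arrays with the mean and SD of 3 arrays per muscle. Slow-type MYBPC1 and HOXA10 (so called by its title, with the symbol HOXD10A) lie higher in soleus, and the transcript similar to slow myosin heavy chain (MYH7-like) lies lower, with none past the adjusted threshold.

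Markers of other cells and of stress had 1 named gene per list, and none passed. Myelin basic protein (MBP), of the nerve and Schwann cell list, had a mean of 0.47 ± 0.11 in longissimus dorsi and -0.44 ± 0.11 in soleus (adjusted p = 0.269). LAPTM5, of the leukocyte list, differed by 0.65 (adjusted p = 0.479). Heat shock protein 20 (HSPB6) differed by 1.06 and 1.10 on 2 probe sets, and heme oxygenase 1 (HMOX1), of the acute stress list, by 1.70 (SE 0.37, adjusted p = 0.330). In 7 of the 19 lists no gene was named among the kept probe sets. These were the tricarboxylic acid cycle, the respiratory chain and ATP synthase, fatty acid uptake and oxidation, fast fibre and myogenic regulators, endothelial markers, adipocyte markers, and the ubiquitin proteasome and autophagy list. As gene names were at hand for the kept probe sets alone, the levels of their members, and those of MYH1, MYH2, TNNT1, TNNT3, PPARGC1A, MB and PITX1, were not analysed here.

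The authors' deposited table listed 550 probe sets at an unadjusted p-value cut-off of 0.05 and a fold cut-off of 1.5, with 323 higher in soleus and 227 higher in longissimus dorsi. The median fold in the authors' deposited table was 1.75 and the largest 30.6. Of its 550 probe sets, 1 was a reporter control, and the other 549 passed the same 2 limits in the limma fit in the same direction. In 549 of 549 the 3 arrays of one muscle did not overlap those of the other. Both counts are close to built in, because the authors' selection was made on these same values. They are not independent evidence. Among the named genes, 173 had a median difference above 0 (higher in soleus) and 115 below.

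Arrays of one muscle were on average more alike than arrays of different muscles, but not in every pair. Correlations of the centred values across probe sets, which are not independent replicates, were 0.30, -0.29 and 0.02 between pairs of longissimus dorsi arrays and -0.13, -0.09 and 0.19 between pairs of soleus arrays. The 9 pairs of different muscles had correlations of -0.48 to 0.01, with a mean of -0.22 against 0.00 for the 6 pairs of one muscle. Centring each probe set over the 6 arrays lowers all such correlations. They can be set against each other, but not against 0. Soleus replicate 3 had the widest values, with an SD over probe sets of 0.50 against 0.24 to 0.31 on the other arrays. It scored 68.3 on the first principal component (44.8% of the variance), with the other 5 arrays between -28.8 and 5.10. The dap and thr control transcripts, bacterial RNAs added to a sample to follow labelling, had means of -0.49, 0.24 and 0.95 on soleus replicates 1, 2 and 3 and of 0.03, -0.20 and -0.04 on those of longissimus dorsi.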

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

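The variance trend, the authors' test with adjustment, and all alternatives for the count of 1219 and for list medians were chosen after seeing the data. The 2 adjusted calls became 7 (3 higher and 4 lower in soleus) with a replicate block and 6 with quantile normalization. They became 10 with a variance trend on the mean centred value, which is not a trend on intensity, and 1 to 4 when each array was left out in turn. They became 1219 at the threshold of unadjusted p and 1.5-fold. The authors' test with Benjamini-Hochberg adjustment gave 2 calls, 1 of them shared. The causes were not tested. The probe set without a gene name passed in 10 of 10 settings (adjusted p of 2.18e-06 to 0.0358) and OCA2 in 8 of 10. The count of 1219 ran from 797 to 2501 over the left-out arrays and was 549 with the unpaired test of the authors' table, which takes no spread from other probe sets, and 1688 with the replicate block. The share higher in soleus was 56.8%, 56.3% after quantile normalization and 50.4% with the block, and over the left-out arrays it ran from 49.4% without soleus replicate 1 to 64.8% without soleus replicate 3. The labels do not say that a replicate number marks a pig. Deviations of same-numbered samples correlated at -0.14, 0.11 and 0.25, and the samples of replicate 3 correlated best with their own number, whereas those of replicates 1 and 2 correlated best with each other's. Over 60 named probe sets and 10 settings, no difference changed sign. Of the 600 comparisons, 585 stayed on their side of the threshold, 13 came past it and 2, both OCA2, lost the call. The 13 were tenascin-X and the ubiquitin-conjugating enzyme E2E 3 with quantile normalization and with the trend, transforming growth factor beta induced and ribonuclease H2 subunit B with quantile normalization, elastin, annexin A8 and TNC with the trend, renalase with the trend and with the authors' test, and arginase type II with the trend and with the replicate block (adjusted p = 0.00190, with a range of 0.00190 to 0.612 over its alternatives). The matrix list's median difference of 1.17 ran from 1.02 to 1.33 and the tendon list's of 1.13 from 0.84 to 1.36 over the left-out arrays. Since listed genes were picked from these arrays, their unchanged direction says nothing about stability. Of the 549 listed probe sets, 549 passed with the replicate block and 429 to 520 without an array. The filters on dim probe sets, the offset before log2, the gene counts and the camera and fry tests were not run, because centred values hold no intensity and names cover the kept probe sets alone. Signal over background is unknown for the same reason.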

Other observations

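All tests and title groups in this part were chosen after the results were seen. The genes below were kept for differing in these samples and were grouped by title after their directions were seen, so their counts are descriptions and no test is given. All 11 genes with collagen titles (15 probe sets) had higher means in soleus. They include members of the matrix list, beside types IV, VIII, XVI and XVIII, which are not in that list. COL8A1, a short-chain collagen, differed by 0.64 and the type XVI chain by 1.22. The 5 genes with mitochondrial titles all had lower means in soleus. They were the mitochondrial ribosomal proteins S26 (-1.08) and S16 (-0.65), the inner membrane peptidase 2-like protein (-0.92), the MMP37-like protein and ALDH2 (-0.65), and none encodes a respiratory chain subunit.

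Cathepsins B, H and Z, lysosomal proteases, had higher means in soleus, by 0.67, 0.87 and 0.72, and the 3 genes with ubiquitin titles had lower ones. Zinc finger titles ran both ways (2 higher, 4 lower). Smooth muscle myosin heavy chain 11 differed by 1.45 and the smooth muscle calponin CNN1 by 0.75, filamins A and B by 0.87 and 0.88, and TGFB1 and TGFB3 by 0.89 and 0.99. RXRG, a retinoid receptor, differed by -1.42, aquaporin 3 by -1.87 and myosin binding protein H by -1.51. None passed the adjusted threshold.

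With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split called 2 probe sets past the adjusted threshold, and the highest other split called 0. At unadjusted p and 1.5-fold it gave 1219 against 1028, by the authors' test 549 against 491, and in each case 1 of the 10 splits, the real one, gave a value as large. At unadjusted p under 0.05 alone the real split gave 2025, and 2 other splits gave more (2289 and 2151). When 500 probe sets were chosen on 2 arrays per muscle, 57.6% to 87.4% kept their sign in the left-out pair, on average 73.2%, against 67.1% for the highest other split.

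The matrix genes were higher in soleus by a median of 1.17. After quantile normalization, which evens out the spread of the arrays, the median was 1.12 (SD 0.18 over the 10 genes). Evening out the spread thus left the size of this difference nearly as it was. Other groups of kept probe sets also changed little (elastin titles 1.06 to 0.98, mitochondrial titles -0.81 to -0.85). The small change is therefore not particular to matrix genes and does not exclude unequal spread. Whether unequal spread helped to pick these genes stays open. They had been kept for differing on these arrays, and all 549 listed probe sets kept their sign after quantile normalization. Unequal labelling along the transcript stays open: soleus replicates 2 and 3 had spike 5' minus 3' values (0.25 and 0.55) above every longissimus dorsi array (-0.34 to 0.05), which goes with it, but soleus replicate 1 (-0.17) lay below longissimus dorsi replicates 1 and 3 (-0.01 and 0.05), and its matrix mean was above theirs (0.84 against -0.48 and -0.42) and above that of soleus replicate 2 by 0.54 (SD 0.30 over genes), which goes against it on 1 soleus array. A lower share of muscle cells in the soleus pieces stays open too. The nerve marker MBP (-0.91), 1 gene, goes against more nerve but says nothing of connective or tendon tissue. The leukocyte marker LAPTM5 (0.65) and the smooth muscle genes MYH11 (1.45) and CNN1 (0.75) go with a lower share. So do all 5 named tendon genes (median 1.13), which had been kept for differing on these arrays. The endothelial and adipocyte lists had no named member. A difference between the muscles themselves was not tested apart from these.

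Soleus replicate 3 stood apart from the other arrays. Labelling that reached further along the transcripts is a candidate explanation that these values cannot settle. The dap and thr spikes, which are not pig RNA, had a 5' minus 3' value of 0.55 (SD 0.20 over 6 probe set pairs), above the others at -0.34 to 0.25. The level of the spikes was also highest on this array (0.95, others -0.49 to 0.24), and its values were the widest (SD 0.50, others 0.24 to 0.31). The high 5' minus 3' value cannot be told apart from these, nor can values taken relative to the spikes. Degraded RNA, which lowers the 5' end, stays open. The 5' minus 3' value of actin was 0.60, above the 0.16 of the next array, but relative to the spikes it was 0.05, within the others' -0.23 to 0.17. That of gapdh was 0.011, within the others' -0.009 to 0.048, and relative to the spikes it was -0.54, the lowest of the 6 arrays. The -0.54 came almost wholly from subtracting the spike value of 0.55. No biological explanation was tested for this array.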
